A study of Mus musculus with 374 samples.

How the data were processed

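Single cells from dissected hearts of mouse embryos were sorted into wells, lysed, reverse transcribed and pre-amplified with TaqMan assays, and each assay was then measured on microfluidic arrays of 96 inputs by 96 assays, per the labels' protocols. The authors deposited 1 table of threshold cycles (Ct values) for 81 assays in 374 cells, in which the code 999 stands for a reaction without a Ct. A lower Ct means more template. The instrument software, its threshold and any quality filter are not given in the sources used here. The Ct values were used as deposited, without normalization. No column was identical to another.

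The table's columns are numbered from 1 to 383 and its rows carry assay numbers between 1 and 96, of which 15 are not used. A column was to be given to a zone only where its name matched the label of 1 sample, and 0 names did. Column order and values were not used in place of names. The order of the sample records was set against the column numbers only to see whether runs could differ in zones. The series description names 9 zones and lists 8 of them, and the sample labels give all 9. Assay numbers were not matched to genes, since the table does not pair them.

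Before the data were examined, comparisons between zones, lists of marker genes, a rule for naming genes and alternatives for each comparison had been fixed. They assumed that columns could be given to zones and assays to genes. None of the zone comparisons, marker-based cell classes, marker-gene clusters, normalization to housekeeping genes, zone prediction or gene lists could therefore be run. The rule for named genes was to take the largest differences between zones that held in both ranges of cell numbers in the titles, and could not be applied either. Kept from the fixed settings were the detection limit of Ct 28, the minimum of 10 assays detected per cell, the absence of normalization and Ward clustering into 3 clusters, here over all 81 assays in place of the marker genes.

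The alternatives for the detection limit, the cell filter, the number of clusters, k-means and centring had also been listed before. Chosen after the values were seen were the link rule, the sets A, B and C, the rule for a positive cell, the runs of 96 column numbers and each assay named in the text. Correlations and hierarchical clustering of the assays were looked at first, and link thresholds of 50, 60 and 70 percentage points were all looked at before 60 was taken. The sets were thus found and described on the same cells, and the shares within and between them are descriptions of these cells.

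Detection shares were computed with exact Clopper-Pearson intervals at 95% (scipy 1.17.1), which cover counting error only. For a count of 0, the upper limit is the share that 3 counts would give. For each pair of assays, the share of cells with one assay was compared between cells with and without the other, in both directions. A pair was linked when both differences reached 60 percentage points, and linked pairs that shared an assay were joined into sets. The shares were not adjusted for the number of assays detected in a cell, which can raise co-detection of any pair. For clustering, Ct values were turned into 28 minus Ct, with 0 for reactions not detected. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scikit-learn 1.9.0, and plots used matplotlib 3.10.9.

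The link rule was tested on simulated data with 81 assays, 334 cells and 3 planted sets holding 34 pairs. With the planted assays detected at random in 5% of the other cells, 30 of the 34 pairs were found, and the 4 missed pairs belonged to the smaller sets. This first simulation had been set up to require all 34, and a lower background of 2% was added after it fell short. At 2%, 34 were found. Rare sets near the threshold can thus be missed, as they were at 5%. No other pair was called in either simulation, but the assays outside the planted sets were drawn independently of each other. The simulated cells also had no built-in difference in the number of assays detected. Links that arise from that number could therefore not appear, and the simulations do not test for them.

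The precision of each share is set by the number of cells, between 79 and 90 per run and 334 in all. The labels name no animal, so spread between animals was not measured. Doublets were not called, since the assay numbers give no markers to call them by. Alternatives tried were detection limits of Ct 24, Ct 26 and every Ct, no cell filter, link thresholds of 50 and 70 points, a positive call only when every assay of a set was detected, leaving out each run, 2 or 4 clusters, k-means and centring each cell on its mean.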

Results

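Expression was measured by quantitative PCR in 374 single cells from mouse hearts at embryonic day 10.5. The cells carried green fluorescent protein after recombination by Cre expressed from the Nkx2-5 locus, which encodes a transcription factor of the early heart. Hearts were dissected into 9 zones before the cells were sorted, with 1 cell per well. The labels assign 47 cells to the atrioventricular canal, 47 to the left ventricle and 36 to the right ventricle. They assign 45 cells to the left septum and 40 to the right septum, and 40 each to the left atrium and the right atrium. The proximal outflow tract has 40 cells and the distal outflow tract 39.

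The probes were chosen to tell apart cell types and anatomical origin, so the design implies comparisons between zones. The columns of the table analysed here carry running numbers, and 0 of the 374 column names matched a sample label. The table numbers its 81 assays and does not pair the numbers with gene names. Differences between zones and named genes were therefore not analysed here, and all cells were treated as 1 sample. The values below describe which numbered assays were detected together in the same cells. With 1 sample there are no replicates, no test was made between groups, and exact 95% binomial (Clopper-Pearson) intervals cover counting error only.

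A threshold cycle (Ct), the PCR cycle at which product is detected, of at most 28 counted as detection. Of 30294 reactions, 12242 met this limit, or 40.4% (95% interval 39.9 to 41%). No Ct was given for 17330 reactions (57.2%). The Ct values ranged from 9.37 to 38.95, with a median of 20.3. At least 10 assays were detected in 334 cells, which were kept. A kept cell had a median of 39.5 assays detected, with quartiles of 28.25 and 43 and a range of 10 to 65.

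The column numbers fall into 4 runs of 96, the number of inputs of 1 array, with 10 numbers not used. Taking these runs as possible technical batches, the median kept cell had 40 assays in run 1, 41 in run 2, 31 in run 3 and 39.5 in run 4. The 40 cells under the minimum comprised 11 in run 1, 16 in run 2, 8 in run 3 and 5 in run 4. No label states that a run is an array or which zones a run holds. In the order of the sample records, however, the labels fall into 4 blocks of 95, 95, 89 and 95 samples that differ in their zones, the same sizes as the runs, and the 9 unused column numbers within runs 2 to 4 lie where title numbers are missing in that order. Order was not used to give columns to zones, but a difference between runs below can be a difference between zones. Run and zone were not told apart here. The first block held all 9 zones, as did the later blocks together, though in other proportions. Zones therefore bear less on a difference between run 1 and the other runs together.

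**Figure D1:**
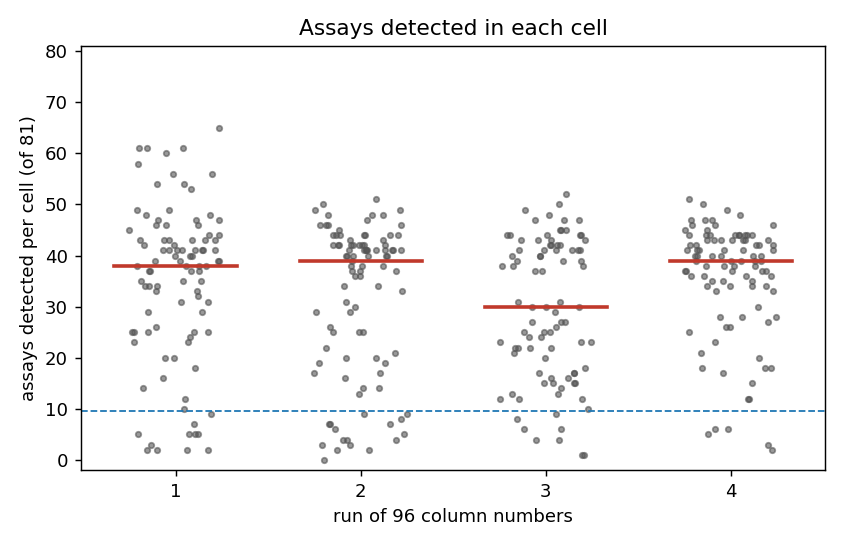
Number of assays detected (Ct at or below 28, of 81) in each of the 374 cells, by run of 96 column numbers, with 1 point per cell, shifted sideways at random for legibility. Red lines mark the median over all cells of a run, which is 38 in run 1, 39 in run 2, 30 in run 3 and 39 in run 4, and the dashed line marks the minimum of 10 assays.

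Detection differed widely between assays. Assay 94 was detected in 327 of 334 cells (97.9%, interval 95.7 to 99.2%) at a median Ct of 14.06, and assay 17 in 313 cells (93.7%, interval 90.5 to 96.1%) at a median Ct of 17.69. These were the 2 assays found in at least 90% of cells. In all, 31 assays were detected in at least 50% of cells. At the other end, assay 29 was detected in 16 cells (4.79%, interval 2.76 to 7.66%), assay 66 in 18 cells (5.39%) and assay 72 in 30 cells (8.98%), the 3 assays under 10%. That call depends on the detection limit: with every Ct counted assay 66 reached 12.7%, and at Ct 24 it was detected in 2.42% of cells, as was assay 29, and 8 assays lay under 10%. Without the minimum of 10 assays per cell, 1 assay, assay 94, was detected in at least 90% of cells. The median assay was detected in 40.7% of cells. The earliest median Ct over all kept cells, 12.94, belonged to assay 1, which was detected in 147 cells (44%, interval 38.6 to 49.5%), whereas assay 50 combined an early median Ct of 14.15 with detection in 288 cells (86.2%, interval 82.1 to 89.7%). Within run 2 assay 1 was not the earliest, with a median Ct of 14.47 against 13.79 for assay 50. The pooled share of assay 1 includes run 4, where it was detected in 0 of 90 cells.

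**Figure D2:**
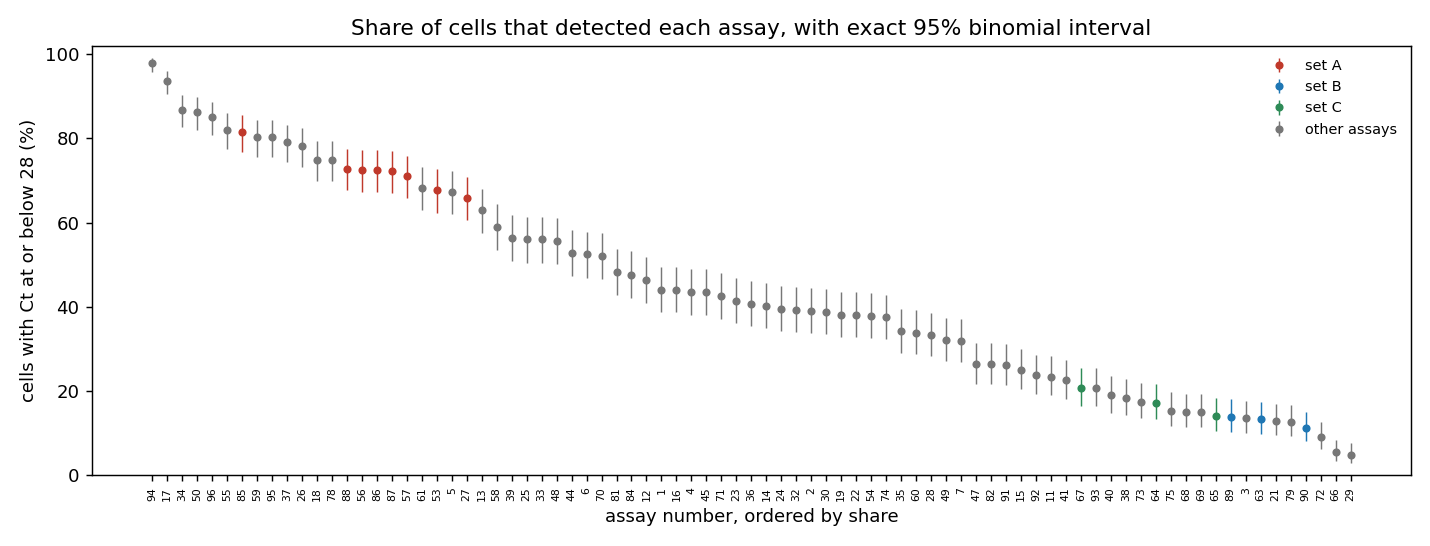
Percent of the 334 kept cells in which each of the 81 assays was detected, ordered by share, with vertical lines for the exact 95% binomial interval. Colours mark the co-detected sets A (8 assays), B (3 assays) and C (3 assays); the assays of set A lie between 65.9 and 81.4%, and those of sets B and C lie at or below 20.7%.

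Groups of assays were detected in the same cells. An assay pair was called linked when the share of cells with either assay was at least 60 percentage points higher among cells with the other assay than among cells without it. Of 3240 pairs, 26 were linked, and they joined 18 assays into 5 sets. Set A held 8 assays (27, 53, 56, 57, 85, 86, 87 and 88), with 19 of its 28 pairs linked. Set B held assays 63, 89 and 90, and set C held assays 64, 65 and 67. Every pair of set B was linked, whereas in set C assays 65 and 67 were each linked to assay 64 only. The remaining sets were the pair of assays 2 and 74 and the pair of assays 70 and 81.

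Within set A, assay 88 was detected in 231 of 241 cells with assay 87 (95.9%, interval 92.5 to 98.0%) and in 12 of 93 cells without it (12.9%, interval 6.85 to 21.5%). Within set B, assay 90 was detected in 36 of 44 cells with assay 63 (81.8%, interval 67.3 to 91.8%) and in 1 of 290 cells without it (0.345%, interval 0.009 to 1.91%). Within set C, assay 67 was detected in 47 of 57 cells with assay 64 (82.5%, interval 70.1 to 91.3%) and in 22 of 277 cells without it (7.94%, interval 5.04 to 11.8%). All 26 linked pairs had a positive difference in each of the 4 runs. In 25 of them the smaller of the differences was at least 30 points in every run, and the lowest, 26.6 points, belonged to assays 2 and 74 in run 4. The pairs had been chosen on these same cells pooled, so the runs are no independent check. Every linked pair of sets B and C fell under 60 points in some run, down to 48.7 in set B and 38.8 in set C. Some pairs of set A did so too, down to 39.1 for assays 56 and 87 in run 1. The number of linked pairs was 43 without the minimum of 10 assays per cell, 51 at a threshold of 50 points and 12 at 70 points.

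**Figure D3:**
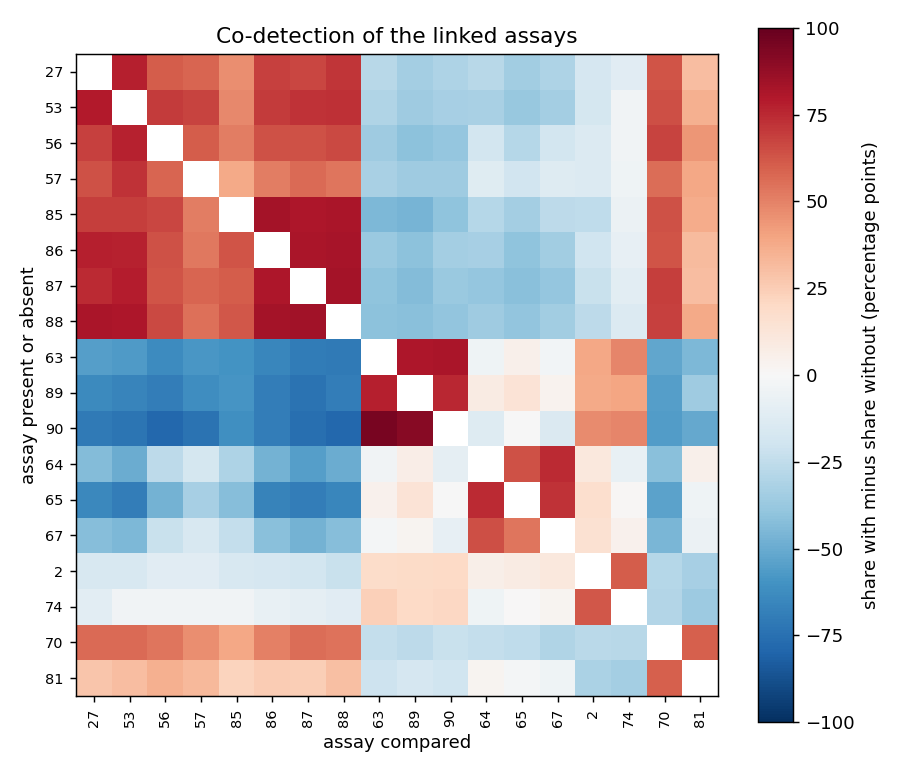
Co-detection of the 18 linked assays in the 334 kept cells. Each square gives the percent of cells with the column's assay among cells with the row's assay minus the percent among cells without it, in percentage points, with blue for negative and red for positive differences; set A forms the large red block, sets B and C the smaller ones, and most squares between set A and sets B or C are blue.

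Set A was rarely found in the same cells as set B or set C. A cell was called positive for a set when more than 50% of the set's assays were detected. By this rule 235 cells were positive for set A (70.4%, interval 65.1 to 75.2%), 40 for set B (12%, interval 8.70 to 15.9%) and 54 for set C (16.2%, interval 12.4 to 20.6%), and 22 cells were positive for none of the 3. With every assay of a set required instead, 35 cells were positive for set C and 87 for none. Run 3 held 20 of the 40 cells positive for set B, and without that run the share was 20 of 253 cells (7.91%, interval 4.90 to 11.9%). Set C was positive in 25% of cells in run 1, 8.86% in run 2, 7.41% in run 3 and 22.2% in run 4. Set A ranged from 58% in run 3 to 79.7% in run 2. Set B was positive in 4 of 235 cells with set A (1.70%, interval 0.466 to 4.30%) and in 36 of 99 cells without it (36.4%, interval 26.9 to 46.6%). Set C was positive in 12 of 235 cells with set A (5.11%, interval 2.67 to 8.75%) and in 42 of 99 cells without it (42.4%, interval 32.5 to 52.8%). Sets B and C were separate among the 99 cells without set A, where set C was positive in 1 of 36 cells with set B (2.78%, interval 0.07 to 14.5%) and in 41 of 63 cells without it (65.1%, interval 52.0 to 76.7%). By run, these counts were 0 of 5, 0 of 4, 0 of 20 and 1 of 7 cells with set B, and 11 of 18, 7 of 12, 6 of 14 and 17 of 19 cells without it. Among cells with set A the order was the opposite, with set C positive in 3 of 4 cells with set B (75%, interval 19.4 to 99.4%) and in 9 of 231 without it (3.90%, interval 1.80 to 7.27%). Over all cells these opposite orders gave 4 of 40 cells (10%, interval 2.79 to 23.7%) and 50 of 294 cells (17%, interval 12.9 to 21.8%).

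Within each run, sets B and C were positive in a lower share of cells with set A than of cells without it, on smaller counts. Set B accompanied set A in 3 of 61 cells of run 1, 0 of 63 of run 2, 0 of 47 of run 3 and 1 of 64 of run 4. Without set A, it was positive in 5 of 23, 4 of 16, 20 of 34 and 7 of 26 cells of these runs. For set C the corresponding counts with set A were 10 of 61, 0 of 63, 0 of 47 and 2 of 64 cells, and without set A 11 of 23, 7 of 16, 6 of 34 and 18 of 26 cells. Across the runs, 13 cells were positive for set A and also for set B or C, of which 11 lay in run 1, so that 2 were left without that run. A positive call for set A is a range and not a cell type, and 27 cells had 4 or 5 of its 8 assays, next to the dividing line.

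Single assays also parted from set B. Assay 63 of set B was detected in 10 of 288 cells with assay 50 (3.47%, interval 1.68 to 6.29%) and in 34 of 46 cells without it (73.9%, interval 58.9 to 85.7%). Assay 90 of the same set was detected in 5 of 288 cells with assay 50 (1.74%) and in 32 of 46 without it (69.6%, interval 54.2 to 82.3%). Assay 89 was detected in 4 of 241 cells with assay 87 of set A (1.66%, interval 0.454 to 4.2%) and in 42 of 93 cells without it (45.2%, interval 34.8 to 55.8%). For assays 50 and 63 the counts by run were 5 of 76, 1 of 71, 3 of 59 and 1 of 82 cells with assay 50, against 6 of 8, 4 of 8, 18 of 22 and 6 of 8 cells without it.

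The runs differed in single assays. The share of kept cells differed by at least 30 percentage points between the highest and the lowest run for 22 of the 81 assays. Assay 1 was detected in 62 of 84 cells of run 1 (73.8%, interval 63.1 to 82.8%), 29 of 79 of run 2 (36.7%, interval 26.1 to 48.3%) and 56 of 81 of run 3 (69.1%, interval 57.9 to 78.9%). In run 4 it was detected in 0 of 90 cells, which allows a share of up to 3.33% by the limit of 3 counts and 4.02% by the exact interval, and no Ct of any size was given for it in the 95 columns of that run. Run 2 was highest for assay 49 (65.8%, interval 54.3 to 76.1%, against 11.1% in run 3) and for the linked assays 74 (73.4%, against 21.1% in run 4) and 2 (69.6%, against 21.1% in run 4). Run 4 was highest for assay 84 (67.8%, interval 57.1 to 77.2%, against 19.8% in run 3). Assay 94 was detected in between 95.2% and 100% of cells of each run.

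**Figure D4:**
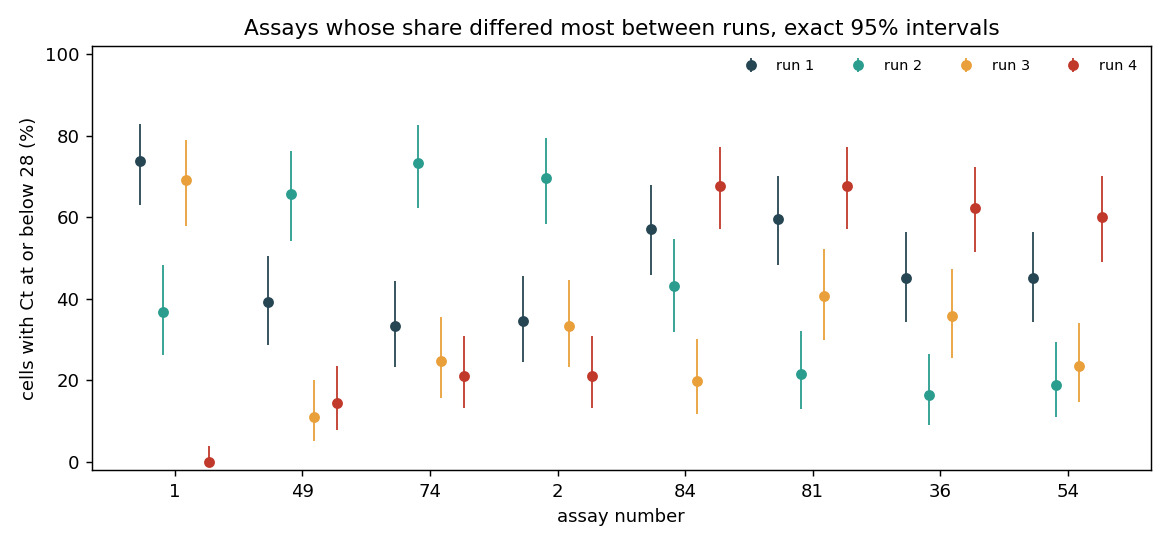
Percent of kept cells with a Ct at or below 28 in each run of 96 column numbers, for the 8 assays whose share differed most between runs, with exact 95% binomial intervals as vertical lines. Assay 1 lies at 0% in run 4, and assays 49, 74 and 2 are highest in run 2.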

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

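In this part, the test of assay failure, the test of a pair of cells in a well and the tests of amplification without template were chosen, wholly or in part, only after the results were seen. Test limits for the mix of cells and for little template were also tightened afterwards.

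A signal lay outside the detection limit: 722 reactions had a Ct above 28, which is 2.38% of all reactions (interval 2.21 to 2.56%) and 5.57% of those with a Ct. Assays 45 (97 reactions), 23 (90), 33 (58) and 16 (56) gave 301 of the 722, or 41.7%, and the next assay gave 31. Amplification without template would give late Ct values about as often in cells with under 10 assays, counted among cells without an early Ct for the assay. The share was 2.5% in such cells and 50.8% in the others for assay 45 (ratio 0.049), 5% and 38.1% for assay 33 (ratio 0.131) and 13.5% and 43.4% for assay 23 (ratio 0.312), with intervals apart. For assay 16 the intervals overlapped (11.8% and 27.8%, ratio 0.423), and over all cells in place of those without an early Ct the intervals were apart for assay 45 alone. Late values were thus rarer in sparse cells for assays 45, 33 and 23. Sparse cells were chosen for few detected reactions, however, and common assays came later in them. Assay 50 had a median Ct of 19.69 there against 14.15 in kept cells. The test cannot tell absent template from wells that reacted poorly, so amplification without template stays open. Little template overall would give a later Ct for assay 94. For assay 45, assay 94 was at a median Ct of 13.77 in cells with a late and 14.24 in cells with an early value (difference -0.47 cycles). Of 96 late cells, 34 lay above the early median (35.4%, interval 25.9 to 45.8%). Assay 94 was not later, but its median Ct also differed between kinds of cells (13.65 with set A only, 15.27 with set C only and 15.42 with set B only). The mix of these cells was not controlled, so little template overall stays open. A low level of this transcript was not tested, and no biological explanation was tested.

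Among the 40 cells left out for having under 10 assays, 27 gave a Ct for assay 94 (67.5%, interval 50.9 to 81.4%), at a median Ct of 16.92 against 14.06 in kept cells. Assay 50 was detected in 28 of them (70%). Other assays common in kept cells were less frequent, with assay 85 in 12 (30%) and assay 17 in 8 (20%).

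Assay 1 had no Ct in run 4. If the mix of cells as the other 80 assays read it were the reason, the 10 most similar cells of the other runs would lack the assay too, but they predicted 71.3% of run 4 cells with it. This argues against that mix as the whole reason, although the same prediction missed by up to 43.9 percentage points in runs with the assay (80.6% predicted and 36.7% observed in run 2). Failure of the assay on 1 array may also be involved, as 0 other assays fell short by at least 50% as much and the next, assay 23, fell short by 23.4 points. It stays open, because the shortfall of 43.9 points in run 2 arose where the assay worked. Other zones in run 4 stay open as part of the reason. The order of the sample records matches the runs in block sizes and in 9 of 9 unused column numbers of runs 2 to 4, and its blocks differ in zones. That order would put the zones of run 4 into run 1 as well, where the share was 73.8%. Zones without the assay would lower run 1 below a mix of runs 2 and 3 (36.7% and 69.1%). This argues against zones as the whole reason if that order holds, but no column was given to a zone and no zone was tested.

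The 13 cells positive for set A and for set B or C had a median of 54 assays detected, against 41 in cells positive for set A only, and 11 of the 13 lay in run 1. Assay 94 was detected in 11 of the 13, against all 222 cells of set A only, 35 of set B only and 41 of set C only. Neither explanation below accounts for its absence. A pair of cells in 1 well could give both sets near their usual Ct, and carry-over of a little product from another well could give the second set late. The assays of sets B and C came a median of 2.6 cycles later in these cells than in cells without set A (38 reactions, quartiles -0.12 and 4.37). This lies between the values that either explanation required. Ct values were not normalized, so a shift between runs may also be part of the delay. Thus 2 cells in 1 well and carry-over cannot be told apart. Cells that express both sets were not tested as an explanation.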

How the results depend on the processing

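The alternatives on numbers of assays, on linked pairs, on sets and on runs were chosen after the data were seen. In kept cells 44.6% of reactions were detected, and this became 40.9% at Ct 24, 43.4% at Ct 26, 46.6% with every Ct and 40.4% without a cell filter. Assays under 10% of cells numbered 3, and 8 at Ct 24, and those in at least 90% numbered 2, and 1 without a cell filter. The 26 linked pairs became 43 without a cell filter, 51 at 50 points and 12 at 70 points, where no pair of set C remained. Leaving out a run gave from 18 pairs (without run 3, all among the 26) to 36 pairs (without run 2, 25 of them shared). With every Ct 22 of the 26 were shared. Cells positive for set A and for set B or C numbered 13, with 8 at Ct 24, 4 when every assay of a set was required and 2 leaving out run 1. Requiring every assay lowered set C from 54 to 35 cells and raised cells with no set from 22 to 87, by the rule's construction. Without a cell filter 62 cells had no set. The cause was not tested for the other shifts. Set B fell from 12% of cells to 7.91% leaving out run 3, and the other shares of sets A, B, C and no set that leave out a run stayed inside the main intervals. Such shares reuse most of the cells and can hide differences between runs, as for set C (25% in run 1 and 7.41% in run 3). Kept cells, assays per cell and numbers of cells of sets A and B stayed within 1.5 times under the limits, the filter and the rule for a positive cell, as did the largest cluster (156 to 214 cells, 205 in the main setting). For 17 assays, nearly all of them named above, 45 of 68 alternative shares stayed inside the main interval and 23 moved outside it. The assays of sets B and C were not among the 17. Not run were the alternatives for comparisons between zones, housekeeping normalization, number ranges of the titles, marker classes, endothelial-like cells and zone prediction, which need zones or genes. No paired analysis was possible because the columns carry no sample numbers of the labels and no result comes from a test. Shares of set B rest on 40 positive cells.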

Other observations

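The observations here were chosen after the values were seen and are given without an explanation. Assays 29 and 66, among the rarest at the limit of Ct 28, were detected together in 8 cells. Of the 7 kept cells without assay 94, 6 had both (85.7%, interval 42.1 to 99.6%), against 2 of 327 cells with it (0.612%, interval 0.074 to 2.19%). In 4 of the 8 cells both were below Ct 16, with assay 29 between 12.81 and 14.81 and assay 66 between 12.45 and 13.39. Of those 4, 3 lacked assay 94 and the other had it at a Ct of 27.4. The 8 cells comprised 5 in run 1, 2 in run 2, 0 in run 3 and 1 in run 4. They had from 20 to 65 assays detected, and the cell with 65 was also among the 13 positive for set A and for set B or C. How many more cells the 2 groups share was not counted.

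Ward clustering of the 334 kept cells over all 81 assays gave clusters of 205, 43 and 86 cells. The largest held 203 of the 235 cells positive for set A, with a median of 42 assays detected. The cluster of 86 held 37 of the 40 cells positive for set B and 44 of the 54 positive for set C. The cluster of 43 had a median of 16 assays and held 28 cells positive for set A and 0 positive for set B. The 3 clusters took 53, 11 and 20 cells from run 1, 57, 10 and 12 from run 2, 37, 17 and 27 from run 3, and 58, 5 and 27 from run 4. With 4 clusters, 36 cells parted from the largest, and 28 of these lay in run 2. The clusters were not named, since the assays were not matched to marker genes.

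Cells positive for a single set differed in how much was detected. The median was 41 assays in the 222 cells of set A only, 33 in the 41 cells of set C only and 24 in the 35 cells of set B only, and assay 94 had median Ct values of 13.65, 15.27 and 15.42 in them. In the 22 cells with no set the median was 17.5 assays. The panel's make-up by cell type was not known here, so these numbers do not compare the RNA content of cells.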
